A study of Mus musculus with 12 samples.

How the data were processed

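Liver RNA of male C57BL/6 mice aged 12 weeks was measured on 12 Affymetrix whole-transcript arrays. Per the labels, the samples fell into 3 groups of 4: males with lean control parents, F2 grandsons of obese Avy/a females and F3 great-grandsons of such females. Avy/a mice carry the viable yellow allele of the agouti gene, which leads to obesity. The labels do not say to which generation each control male belonged. Total RNA was extracted with Trizol and labelled with biotin using a whole-transcript kit, per the labels' protocols. Nothing in the labels says that the replicates were separate animals, so p-values measure the spread between these samples, part of which may be technical. The number of arrays limits the precision.

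The deposited values were log2 expression values per probe set, 1 column per array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The software version, the background correction, the normalization and the summarization algorithm are not given in the sources used here. The log2 scale was read from the values, which ran from 0.73 to 13.64 with no missing entries. Medians per array lay between 4.49 and 4.60, so the arrays were close in scale but not forced to be equal. No pair of arrays held identical values, and the mean absolute difference between pairs ranged from 0.159 to 0.353.

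The table held 72688 probe sets, of which 6732 were control probe sets. The platform annotation used here listed 32750 probe sets, 30604 with 1 gene symbol and 2146 with several. The remaining 39938 were unnamed here. Of the probe sets with 1 symbol, 23054 had an Entrez identifier, 22818 of these matched a RefSeq gene table of the assembly GRCm38.p6, and 827 symbols were updated from it. That table was used for names and gene classes only. No genome build was named for the array values, so no coordinates are given. Probe sets with 1 symbol represented 30142 genes, and for the 355 genes with several probe sets the one with the highest mean over the 12 arrays was used.

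Genes were tested where their mean over the 12 arrays was above 4.55, the median of all probe sets. This left 18725 genes, of which 13559 were protein coding. The filter was lenient: 57.0% of 5222 negative control probe sets and 7.02% of 1324 positive control probe sets lay under it, so genes near background remained among those tested.

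All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, 9 residual degrees of freedom), with no covariate. The contrasts were F2 minus control, F3 minus control, F3 minus F2, and the mean of F2 and F3 minus control. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Intervals are 95% confidence intervals from limma. A list of 22 liver metabolic genes was also adjusted over the list alone. The names of the members without a usable probe set are not reported here. Another 43 gene lists, covering metabolic and stress pathways, chromatin enzymes, imprinted genes and markers of cell types, were tested with limma's camera at its preset inter-gene correlation of 0.01, in either direction, with Benjamini-Hochberg adjustment over the 43 lists of a comparison. Camera compares the genes of a list with all other genes. Camera with an estimated correlation and fry were run as alternatives. A list's score in an array is the median over its genes of the log2 value minus the gene's mean over the 12 arrays, and differences of scores between groups were tested with exact permutation tests.

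For F2 and F3 against control, up to 10 genes per direction were named by lowest p among genes that passed the threshold, had all 4 descendant arrays on one side of all 4 control arrays and differed by at least 0.3. Where fewer qualified, the places were filled by lowest unadjusted p under the same range and size conditions, and such genes are reported as not passing. Genes with predicted or RIKEN names, microRNAs and small RNAs were counted but passed over in that fill. Every measured gene of the metabolic list, and the 4 members with the lowest p of each list that camera called, were named as well. For F3 against F2, up to 5 genes per direction that passed the threshold were to be named. The groups, contrasts, lists, naming rule and the alternative settings listed first in the next paragraph were fixed before the data were examined.

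The alternative settings were quantile normalization, centring on array medians, no filter, a stricter filter (mean above 5.92, the 75th percentile), the mean over a gene's probe sets, every probe set as the unit, eBayes with trend and robust, array weights, only the arrays of the groups compared, the replicate number as a block, leaving out each array in turn, an adjusted p under 0.10, and an unadjusted p under 0.05 with a 1.5-fold difference. The array set described in the results as a block, each array set alone, and the fit without control replicate 2 and F2 replicate 2 were added after seeing the data.

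The code was tested on simulated data built on the 18725 genes and the F2 against control comparison, with 200 genes changed in each of 20 simulations. It called 63.7% of genes changed by 0.5, 94.6% of those changed by 1 and 98.6% of those changed by 2 on the log2 scale, and 0.058% of unchanged genes. The changed genes were drawn at random, and the median SE of the genes tested was 0.089 in F2 against control. These shares do not hold for genes with a larger SE, such as the fatty acid synthase gene Fasn (0.42). For lists without any effect, camera with the preset correlation called a mean of 12.8 of 43 lists per simulation and at most 22, while camera with an estimated correlation called 0. A list of oxidative phosphorylation genes shifted by 0.5 was called in 20 of 20 simulations with the preset correlation and in 19 with an estimated one.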

Results

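Liver expression was compared between males with lean control parents, F2 grandsons and F3 great-grandsons of obese Avy/a females, with 4 arrays per group. The comparison asks whether obesity of a female ancestor is followed by altered liver expression in later generations of males. Across genes, which are not independent replicates, log2 values of any 2 arrays correlated with r between 0.967 and 0.993. The median r was 0.986 within groups and 0.986 between groups.

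The arrays separated by their content of small structural RNAs rather than by group. Small nucleolar RNAs (337 genes) guide chemical modification of ribosomal RNA. They averaged 6.38 ± 0.04 (SD, n = 7) in a higher set of arrays and 5.95 ± 0.06 (SD, n = 5) in a lower set. The 2 sets were made by a cut at the widest gap in this level, so their difference in it follows from the cut. The higher set held control replicates 2 and 4, F2 replicates 1 and 4, and F3 replicates 1, 2 and 3. Y RNAs, short RNAs bound by the Ro protein, differed between the sets by 1.04, ribosomal RNA by 0.62 and small nuclear RNAs of the spliceosome by 0.43, each without overlap. The first principal component carried 41.2% of the variance. Within a set, arrays correlated with a median r of 0.991, against 0.984 between sets. No technical label divides the arrays this way, so the sets are a feature of the data, and values with the set as a block and within each set accompany the counts.

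**Figure D1:**
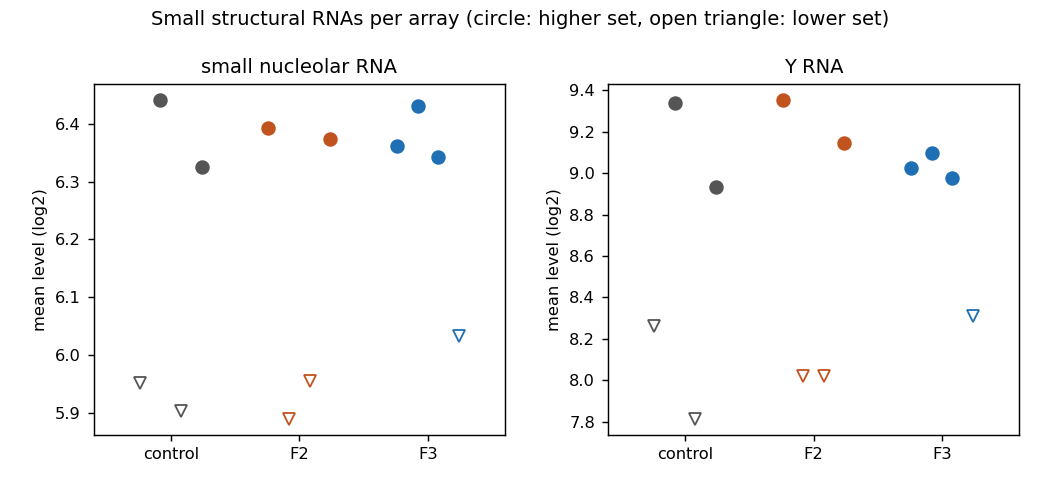
Mean log2 level of 337 small nucleolar RNA genes (left) and 2 Y RNA genes (right) on each of the 12 arrays, by group. Circles are the arrays of the higher set and open triangles those of the lower set, and every group has arrays in both sets. The sets were cut at the widest gap in the level on the left.

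In F2 males, Fasn, which encodes fatty acid synthase, had the largest difference from control of the genes tested. It averaged 9.76 ± 0.81 (SD, n = 4) in F2 and 10.90 ± 0.48 (SD, n = 4) in controls, a log2 difference of −1.14 (SE 0.42). Acly, which supplies cytosolic acetyl-CoA, differed by −0.85 (SE 0.38), Thrsp, a lipogenic regulator, by −0.72 (SE 0.33) and Elovl6, a fatty acid elongase, by −0.60 (SE 0.26). Igf1, the liver-derived growth factor, was 0.32 higher (SE 0.12) and lay above all 4 control arrays in all 4 F2 arrays, with 0.18 left without control replicate 2. None of these differences passed the test. Limma called 0 of 18725 genes (smallest adjusted p = 0.9999). An unadjusted p under 0.05 was reached by 172 genes (64 higher, 108 lower), where 936.25 are expected by chance. The fit had no term for the array sets, which lie within every group, and genes vary together. The count under the expected one is therefore not evidence of no change. The 95% interval of the difference lay within 2-fold for 98.5% of genes and within 1.5-fold for 95.2%. These shares include genes near background and do not hold for every gene. The interval was −2.04 to −0.23 for Fasn and −1.53 to 0.75 for the leptin receptor gene Lepr, so larger differences were not excluded there.

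F2 and control arrays did not overlap for 132 genes (0.705%), where chance alone gives 2.86%. This low share is likewise not evidence of no change. Of these 132 genes, 12 differed by at least 0.3. The 4 higher ones named by the rule, none passing the test, were Ldha-ps2 (0.43, SE 0.14), Arsg, a lysosomal sulfatase (0.31, SE 0.11, and 0.19 without F2 replicate 2), Igf1 and the olfactory receptor gene Olfr1034 (0.31, SE 0.12). Ldha-ps2 is a processed copy of the lactate dehydrogenase gene Ldha, whose probe set was 0.26 higher (SE 0.089), so its value is uncertain. Both lower ones named were Cyp2a4, a female-biased steroid hydroxylase (−0.61, SE 0.29), and Map3k13, a stress kinase (−0.38, SE 0.21). F2 replicate 2 was far below the other F2 arrays for both, and without it the differences were −0.28 for Cyp2a4 and −0.21 for Map3k13. A further 5 higher genes and 1 lower gene were passed over by name (predicted, RIKEN or small RNA genes).

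Camera with the preset correlation called 14 of 43 gene lists in F2, 4 higher and 10 lower. Over all 35 splits of the F2 and control arrays the median was 13 lists. Of the 73 single genes followed when arrays were left out, 54 had a difference that turned in sign or shrank by over 1.5 times without some 1 array, against 34 of 57 in F3 and 29 of 45 between F3 and F2. Cholesterol synthesis genes were called lower, with 18 of 18 members below control (median −0.37, adjusted p = 1.87e-08), and with adjusted p = 0.654 with an estimated correlation. Among them Insig1, a sterol sensor, differed by −0.46 (SE 0.21), Lss, lanosterol synthase, by −0.50 (SE 0.27), Mvk, mevalonate kinase, by −0.27 (SE 0.14) and Fdps, farnesyl diphosphate synthase, by −0.71 (SE 0.43). Control replicate 2 had the highest score for these genes, 1.09 against at most 0.33 elsewhere. Without it the median was −0.04 (adjusted p = 0.865), with Fdps at −0.26, Lss at −0.17 and Mvk at −0.12, and within the lower set of arrays it was 0.01. Fatty acid and triglyceride synthesis was called lower, with 17 of 24 members below control (median −0.13, adjusted p = 2.86e-05), and with adjusted p = 0.654 with an estimated correlation. That call ended without control replicate 2 (adjusted p = 0.269) or without F2 replicate 2 (adjusted p = 0.284).

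Lists of energy metabolism and detoxification were called lower too, each with adjusted p = 0.654 with an estimated correlation. Oxidative phosphorylation genes lay lower in 40 of 43 members (median −0.06, adjusted p = 4.25e-06), with Atp5a1, a subunit of ATP synthase, at −0.10 (SE 0.051), the complex II genes Sdhd at −0.12 (SE 0.066) and Sdhc at −0.12 (SE 0.065), and the complex I gene Ndufc2 at −0.10 (SE 0.071). Without F2 replicate 2 their median was −0.01 (adjusted p = 0.672). Glycolysis and glycogen genes lay lower in 20 of 25 (median −0.08, adjusted p = 0.0014), with Gckr at −0.15 (SE 0.063), Pklr, liver pyruvate kinase, at −0.34 (SE 0.17) and Khk, ketohexokinase, at −0.17 (SE 0.089), while Ldha lay above control. That call ended without control replicate 2 (adjusted p = 0.272) or F2 replicate 2 (adjusted p = 0.0703). Xenobiotic metabolism genes lay lower in 19 of 22 (median −0.20, adjusted p = 5.40e-06), with the glutathione transferases Gstm2 at −0.27 (SE 0.084), Gstm3 at −0.49 (SE 0.23) and Gsta2 at −0.56 (SE 0.33), and Cyp2c55 at −0.28 (SE 0.17). Their median without F2 replicate 2 was −0.05 (adjusted p = 0.326). NRF2 antioxidant targets lay lower in 17 of 19 (median −0.14, adjusted p = 5.40e-06), with Pgd of the pentose phosphate pathway at −0.38 (SE 0.16), Nfe2l2, which encodes NRF2, at −0.24 (SE 0.13) and Ugdh at −0.34 (SE 0.19). Here the call ended without control replicate 2 (median −0.06, adjusted p = 0.39), which left Ugdh at −0.13, Gstm3 at −0.25 and Gsta2 at −0.19.

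Acute phase genes, which the liver secretes in inflammation, were called higher in F2, with 25 of 27 above control (median 0.22, adjusted p = 5.12e-07), and with adjusted p = 0.654 with an estimated correlation. Cp, ceruloplasmin, differed by 0.19 (SE 0.11), Crp, C-reactive protein, by 0.25 (SE 0.15), and the fibrinogen genes Fgb and Fgg by 0.16 (SE 0.094) and 0.16 (SE 0.096). Without F2 replicate 2 the list's median was −0.05 (adjusted p = 0.968), with Crp at 0.077 and Cp at 0.11, while in the higher set alone, which lacks that array, it was 0.14 (adjusted p = 0.00861). Glucocorticoid targets were called higher in 12 of 18 (median 0.08, adjusted p = 0.00858), and with adjusted p = 0.654 with an estimated correlation. Pck1, the gluconeogenic enzyme, was at 0.28 (SE 0.12), Fkbp5, a chaperone of the steroid receptors, at 0.30 (SE 0.18), the transcription factor Klf9 at 0.27 (SE 0.17) and the metallothionein Mt2 at 0.92 (SE 0.81, and 0.17 without F2 replicate 2). That call ended without control replicate 3 (adjusted p = 0.215), control replicate 4 (adjusted p = 0.462) or F2 replicate 3 (adjusted p = 0.483). Ribosomal protein genes lay lower in 19 of 21 (median −0.05, adjusted p = 0.00452), and with adjusted p = 0.672 with an estimated correlation. Rps14 was at −0.09 (SE 0.059), Rps15 at −0.11 (SE 0.085), Rpl19 at −0.09 (SE 0.075) and Rplp0 at −0.06 (SE 0.06), and the call ended without control replicates 1 or 2 or F2 replicates 1 or 4 (adjusted p = 0.294, 0.324, 0.0634 and 0.0896).

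Sex-biased genes were called in opposite directions. Male-biased liver genes were called higher in 18 of 26 members (median 0.06, adjusted p = 0.0084) and female-biased genes lower in 12 of 17 (median −0.19, adjusted p = 0.0493), each with adjusted p = 0.693 with an estimated correlation. Among male-biased genes the complement genes C8a and C6 were at 0.34 (SE 0.20) and 0.41 (SE 0.30), the steroid enzyme gene Hsd3b5 at 0.56 (SE 0.42) and Susd4 at −0.31 (SE 0.18). Among female-biased genes Cyp2b9 was at −1.10 (SE 0.76), the transporter gene Slco1a4 at −0.37 (SE 0.28) and Cyp3a44 at −0.24 (SE 0.21). Cyp2b9 stood at 8.50 in control replicate 2 and at no more than 4.49 on any other array, and without that array its difference was −0.016, that of Hsd3b5 −0.031, of C8a 0.099 and of C6 0.076. Slco1a4 was at −0.025 and Cyp3a44 at −0.052 without F2 replicate 2. Without control replicate 2 the medians were −0.04 (adjusted p = 0.743) for male-biased and 0.01 (adjusted p = 0.324) for female-biased genes, so both directions turned, and within the lower set the male-biased median was −0.03 (adjusted p = 0.275). The male-biased call also ended without F2 replicate 3 (adjusted p = 0.369) or F2 replicate 4 (adjusted p = 0.0947). The female-biased call ended without F2 replicates 2 or 3 or F3 replicates 2 or 4 (adjusted p = 0.966, 0.166, 0.0564 and 0.0587).

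Other metabolic lists were not called in F2. Lipid droplet genes had a median of 0.09 (adjusted p = 0.0642), insulin and IGF signalling 0.02 (adjusted p = 0.0626), fatty acid oxidation −0.04 (adjusted p = 0.526), gluconeogenesis −0.01 (adjusted p = 0.513), bile acid synthesis and transport −0.03 (adjusted p = 0.636) and lipoprotein genes 0.00012 (adjusted p = 0.175). The fatty acid oxidation, gluconeogenesis and lipoprotein lists were near 0, and median, mean or test differed in sign. With the array set as a block limma again called 0 genes and camera 15 lists. Within the higher set 0 genes were called and within the lower set 0.

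**Figure D2:**
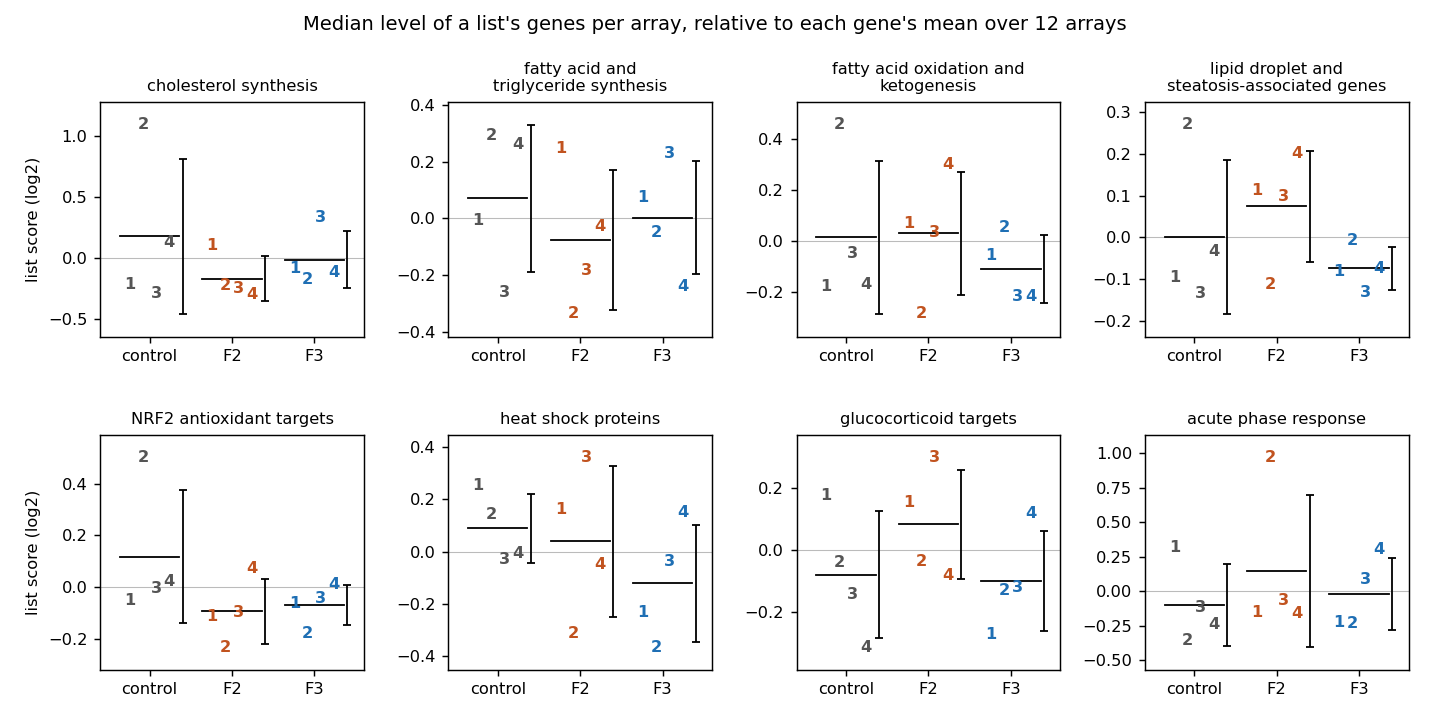
Scores of 8 gene lists on the 12 arrays, as the median over a list's genes of the log2 value minus the gene's mean over all arrays. Digits are replicate numbers, horizontal lines are group means and bars are 1 SD (n = 4). Control replicate 2 lies apart for cholesterol synthesis (1.09) and F2 replicate 2 for the acute phase response (0.97).

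In F3 males the bile acid gene Cyp8b1 lay furthest below control among the fixed metabolic genes. Cyp8b1, the enzyme that directs bile acid synthesis towards cholic acid, averaged 9.84 ± 0.15 (SD, n = 4) in F3 and 10.56 ± 0.28 (SD, n = 4) in controls, a log2 difference of −0.71 (95% interval −1.08 to −0.34), with all 4 F3 arrays below all 4 control arrays. The inducible chaperone gene Hspa1a was at −1.32 (SE 0.54), its co-chaperone gene Dnajb1 at −0.47 (SE 0.16) and the transcription factor gene Fos at −0.41 (SE 0.18), and Cyp2c67, a cytochrome P450 gene, was at 0.47 (SE 0.079). Over all genes limma called 0 of 18725 (smallest adjusted p = 0.9998). An unadjusted p under 0.05 was reached by 548 (308 higher, 240 lower), where 936.25 are expected by chance. As in F2, the lower count is not evidence of no change. The 95% interval lay within 2-fold for 98.5% of genes and within 1.5-fold for 94.1%. As in F2, these shares include genes near background. The interval was wider for some genes, such as Fasn (−1.09 to 0.72) and Lepr (−1.43 to 0.85).

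Cyp8b1 was the 1 gene of the metabolic list that passed when adjusted over the list alone (adjusted p = 0.0204, limma). Over all genes its adjusted p was 0.9998, and over the list and all 3 comparisons, 51 values, the smallest adjusted p was 0.0612. The call over the list alone ended without control replicate 1 (adjusted p = 0.0726), control replicate 2 (adjusted p = 0.0739), F3 replicate 3 (adjusted p = 0.0768) or F3 replicate 4 (adjusted p = 0.0716), with differences between −0.68 and −0.60. With the array set as a block the difference was −0.76 and the adjusted p over the list alone 0.00915, and within the higher set it was −0.71 (adjusted p = 0.0557) and within the lower set, with 1 F3 array, −0.78 (adjusted p = 0.0815).

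F3 and control arrays did not overlap for 305 genes (1.63%), where chance gives 2.86%, a low share that is not evidence of no change. Of these 305 genes, 29 differed by at least 0.3. None passed the test. The higher ones named by the rule were Cyp2c67, Cyp2c40 (0.40, SE 0.082), Cyp2c68 (0.44, SE 0.093), Cyp2c69 (0.40, SE 0.093), the calcium-binding protein gene Necab1 (0.32, SE 0.082), the alcohol dehydrogenase gene Adh4 (0.34, SE 0.088), Rpl17-ps1 (0.31, SE 0.082), the membrane protein gene Tmem141 (0.49, SE 0.14), Rpl31-ps20 (0.31, SE 0.092) and the organic anion transporter gene Slc22a28 (0.30, SE 0.094). The 4 Cyp2c genes are close copies of each other and both Rpl genes are processed copies of ribosomal protein genes, so their probe sets can share transcripts and single values are uncertain. The lower ones were Cyp8b1, the chemokine Cxcl10 (−0.37, SE 0.11), Dnajb1, the chemokine receptor Cxcr4 (−0.31, SE 0.11), Hspa1a, Fos and the lymphocyte antigen gene Ly6d (−0.32, SE 0.28). Cxcl10 averaged 4.75 in controls and 4.38 in F3, near the median of negative control probe sets (4.24), so its difference is uncertain. Cxcr4 was also dim, at 5.03 in controls and 4.71 in F3. A further 10 higher genes and 1 lower gene were passed over by name, and 1 more higher gene qualified beyond the 10 places.

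Camera with the preset correlation called 7 of 43 lists in F3, 2 higher and 5 lower, each with adjusted p = 0.93 with an estimated correlation. The number was 4 without control replicate 2, 12 without control replicate 1 and 16 without control replicate 3. Over all 35 splits of the F3 and control arrays the median was 12 lists, more than the real groups gave. Heat shock proteins lay lower in 16 of 17 members (median −0.16, adjusted p = 3.42e-05 with the preset value), with the mitochondrial chaperone gene Hspd1 at −0.18 (SE 0.075) and the co-chaperone gene Bag3 at −0.61 (SE 0.32), and this call held without each array in turn. Within the lower set of arrays its median was 0.07 (adjusted p = 0.968). Fatty acid oxidation and ketogenesis genes lay lower in 26 of 27 (median −0.13, adjusted p = 0.00324), and with adjusted p = 0.93 with an estimated correlation. Cyp4a14, a fatty acid hydroxylase, was at −1.62 (SE 1.22), Ehhadh of peroxisomal oxidation at −0.65 (SE 0.47), Angptl4, an inhibitor of lipoprotein lipase, at −0.40 (SE 0.28) and Ech1 at −0.24 (SE 0.16). Without control replicate 2, the array with the highest score (0.46), the median was 0.03 (adjusted p = 0.68), with Cyp4a14 at −0.50, Ehhadh at −0.18 and Ech1 at −0.078, and Angptl4 was at −0.22 without control replicate 1. The call also ended without F3 replicate 3 (adjusted p = 0.0801) or F3 replicate 4 (adjusted p = 0.137).

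Immediate early genes lay lower in 17 of 24 (median −0.12, adjusted p = 0.00229), and with adjusted p = 0.93 with an estimated correlation. Ier3 was at −0.19 (SE 0.074), the nuclear receptor gene Nr4a1 at −0.27 (SE 0.12) and the growth arrest gene Gadd45a at 0.22 (SE 0.098), and the call ended without control replicate 1 (adjusted p = 0.0935) or F3 replicate 1 (adjusted p = 0.0722). Inflammatory cytokines and chemokines lay lower in 15 of 16 (median −0.11, adjusted p = 0.00328), and with adjusted p = 0.93 with an estimated correlation. Nfkbia, an inhibitor of NF-kB, was at −0.29 (SE 0.16), Ccl5 at −0.13 (SE 0.084) and Ccl2 at −0.16 (SE 0.12). That call ended without control replicate 1 (adjusted p = 0.314) or F3 replicate 4 (adjusted p = 0.137), and within the higher set of arrays the median was 0.03. NRF2 antioxidant targets lay lower in 15 of 19 (median −0.24, adjusted p = 0.00225), and with adjusted p = 0.93 with an estimated correlation. Srxn1, sulfiredoxin, was at −0.27 (SE 0.11), Ugdh at −0.44 (SE 0.19), Gstm3 at −0.41 (SE 0.23) and Hmox1, heme oxygenase, at −0.35 (SE 0.19), and without control replicate 2 the median was −0.06 (adjusted p = 0.643), with Srxn1 at −0.15, Ugdh at −0.23 and Gstm3 at −0.17. Within the lower set, with 1 F3 array, it turned to 0.09 (adjusted p = 0.0739).

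Male-biased liver genes lay higher in 17 of 26 in F3 (median 0.07, adjusted p = 0.0101), and with adjusted p = 0.93 with an estimated correlation. Slc22a30 was at 0.28 (SE 0.088), the peroxisomal hydrolase gene Nudt7 at 0.29 (SE 0.13), the organic anion transporter gene Slco1a1 at 0.24 (SE 0.11) and C6 at 0.54 (SE 0.30), and the call ended without control replicate 2 (adjusted p = 0.732, with C6 at 0.21 and Nudt7 at 0.15) or F3 replicate 4 (adjusted p = 0.258). Cholesterol synthesis (median −0.20, adjusted p = 0.0593), xenobiotic metabolism (−0.06, adjusted p = 0.0702), acute phase (0.13, adjusted p = 0.0857), female-biased genes (−0.03, adjusted p = 0.72), fatty acid and triglyceride synthesis (−0.02, adjusted p = 0.513) and oxidative phosphorylation (−0.02, adjusted p = 0.22) were not called in F3. Nor were the unfolded protein response (−0.0031, adjusted p = 0.757), the circadian clock (0.0015, adjusted p = 0.913), interferon response (0.004, adjusted p = 0.913), extracellular matrix (0.0031, adjusted p = 0.767), cell cycle (−0.03, adjusted p = 0.72), imprinted genes (0.02, adjusted p = 0.767) and DNA methylation and histone-modifying enzymes (−0.01, adjusted p = 0.72). Within the bile acid list Cyp8b1 was the 1 of 25 members that passed when adjusted over the list alone (adjusted p = 0.03). With the array set as a block limma called 0 genes and camera 14 lists. Within the higher set 0 genes were called, and within the lower set, where the single F3 array was assumed to vary like the other groups, 2.

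**Figure D3:**
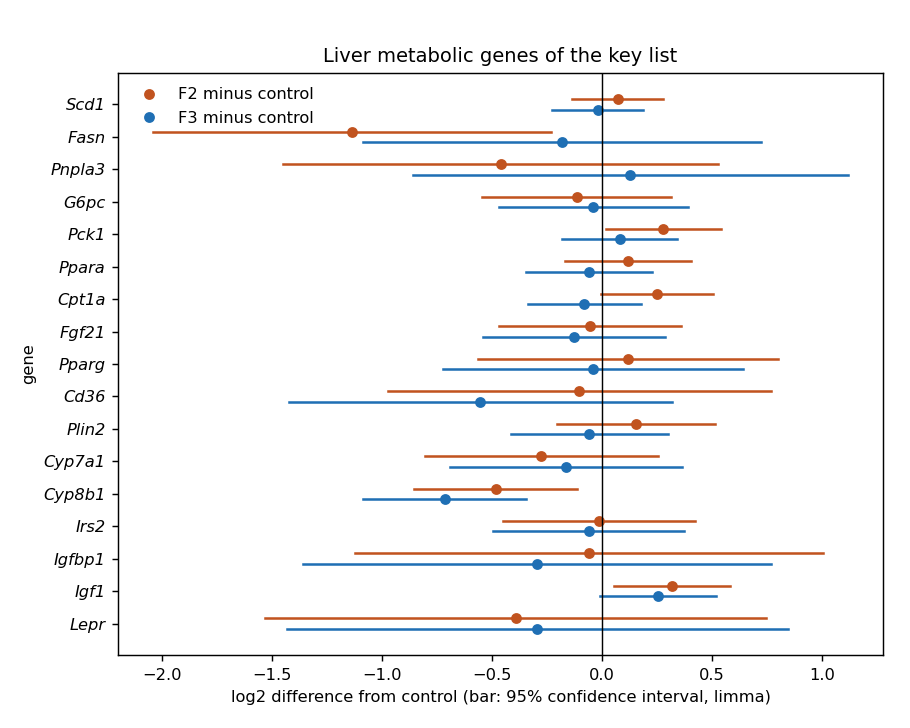
Log2 difference from control of the 17 measured liver metabolic genes in F2 (orange) and F3 (blue), with points for estimates and bars for 95% confidence intervals from limma. Cyp8b1 in F3 (−0.71) is the only value that passed when adjusted over the list alone, and Fasn in F2 (−1.14) has a wide interval.

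Of the 22 metabolic genes, 17 were measured, and the others had no probe set with a single symbol in the annotation used here. In F2, 4 of them had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone or over all genes, by limma. These were Fasn, Cyp8b1 (−0.48, SE 0.17, and −0.31 without F2 replicate 2), Igf1 and Pck1, with a smallest adjusted p over the list alone of 0.124. Without F2 replicate 1, Fasn was at −1.53 and passed over the list alone (adjusted p = 0.0168). In F3, Igf1 was at 0.26 (SE 0.12), Pck1 at 0.08 (SE 0.12) and Fasn at −0.18 (SE 0.42). Cpt1a was at 0.25 in F2 and −0.08 in F3 (SE 0.12), and Cd36, the fatty acid translocase, at −0.10 and −0.55 (SE 0.40), which became 0.42 and −0.031 without control replicate 2. Scd1, a fatty acid desaturase, was at 0.07 in F2 and −0.02 in F3 (SE 0.095), Pnpla3 at −0.46 and 0.13 (SE 0.46, and −0.38 in F3 without F3 replicate 3), G6pc, the catalytic subunit of glucose 6-phosphatase, at −0.11 and −0.04 (SE 0.20), and Ppara, the fasting regulator of fat oxidation, at 0.12 and −0.06 (SE 0.13). Fgf21, a fasting hormone, was at −0.05 and −0.13 (SE 0.19), Pparg at 0.12 and −0.04 (SE 0.31), the lipid droplet gene Plin2 at 0.16 and −0.06 (SE 0.16) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at −0.27 and −0.16 (SE 0.24). Irs2 was at −0.01 and −0.06 (SE 0.20), Igfbp1 at −0.06 and −0.29 (SE 0.49), and 0.52 and 0.29 without control replicate 1, and Lepr, the leptin receptor, at −0.39 and −0.29 (SE 0.52), and −0.015 and 0.083 without control replicate 2.

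The direct comparison of F3 with F2 asks whether the generations differ. None of the genes given here passed the test. Cpt1a, which controls entry of fatty acids into mitochondria, was at −0.33 (SE 0.12), Pnpla2, the adipose triglyceride lipase, at −0.50 (SE 0.17) and Angptl4 at −0.61 (SE 0.28). The lipogenic genes Fasn and Thrsp were at 0.95 (SE 0.42) and 0.89 (SE 0.33). Limma called 0 of 18725 genes (smallest adjusted p = 0.9999), with 443 at an unadjusted p under 0.05 (298 higher, 145 lower), and 0 of the metabolic genes passed when adjusted over the list alone (smallest adjusted p = 0.26, Cpt1a). The 95% interval lay within 2-fold for 98.2% of genes and within 1.5-fold for 94.0%, genes near background included, but ran from 0.049 to 1.86 for Fasn. Without F2 replicate 1, Fasn passed over the list alone (1.35, adjusted p = 0.0415), and without F3 replicate 3 its difference was 0.60 (SE 0.38).

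Camera with the preset correlation called 8 lists between F3 and F2, 1 higher and 7 lower, each with adjusted p = 0.914 with an estimated correlation. The number was 14 without F2 replicate 1 or without F3 replicate 3. Over all 35 splits of the F2 and F3 arrays the median was 12 lists, more than the real groups gave. Lipid droplet genes lay lower in 17 of 21 (median −0.16, adjusted p = 0.000324), with the lipid droplet coat gene Plin4 at −0.39 (SE 0.19), the monoglyceride lipase gene Mgll at −0.27 (SE 0.15) and Cidea at −0.18 (SE 0.097). Glucocorticoid targets lay lower in 16 of 18 (median −0.20, adjusted p = 0.000163), with Errfi1 at −0.18 (SE 0.078), the clock gene Per1 at −0.38 (SE 0.19) and Pck1 at −0.20 (SE 0.12). Both calls held without each array in turn, and both were lost with an estimated correlation, as were those that follow. Fatty acid oxidation genes lay lower in 24 of 27 (median −0.14, adjusted p = 0.000163), with Eci2 at −0.28 (SE 0.19) and Cpt2 at −0.18 (SE 0.12), and the call ended without F2 replicate 4 (median −0.03, adjusted p = 0.282). Heat shock proteins lay lower in 16 of 17 (median −0.15, adjusted p = 0.000172), with Hspa1a at −1.10 (SE 0.54, −0.73 without F2 replicate 3 and larger in size without F2 replicate 2), Dnajb1 at −0.43 (SE 0.16), Bag3 at −0.47 (SE 0.32) and Hspb8 at −0.21 (SE 0.12), and the call ended without F2 replicate 3 (adjusted p = 0.0931). Within the lower set, with 1 F3 array, the heat shock median turned to 0.07 (adjusted p = 0.22), and glucocorticoid targets were not called (adjusted p = 0.889).

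Immediate early genes lay lower in 20 of 24 between F3 and F2 (median −0.06, adjusted p = 0.00213), and with adjusted p = 0.914 with an estimated correlation. Klf2 was at −0.26 (SE 0.099), Zfp36, which destabilises cytokine mRNA, at −0.32 (SE 0.13), Nr4a1 at −0.25 (SE 0.12) and Gadd45a at 0.29 (SE 0.098), and the call ended without F2 replicate 4 (adjusted p = 0.0843) or F3 replicate 1 (adjusted p = 0.144). Inflammatory cytokines lay lower in 12 of 16 (median −0.07, adjusted p = 0.034) and insulin and IGF signalling genes in 21 of 28 (median −0.04, adjusted p = 0.0311), each with adjusted p = 0.914 with an estimated correlation. Cxcl10, which lay near background, was at −0.24 (SE 0.11), Tnfaip3 at −0.23 (SE 0.13), Nfkbia at −0.26 (SE 0.16) and Il1b at −0.33 (SE 0.20). The pseudokinase gene Trib1 was at −0.36 (SE 0.13), Trib3 at −0.16 (SE 0.093), Tsc2 at −0.14 (SE 0.083) and Igfbp2 at −0.23 (SE 0.15). The cytokine call ended without control replicate 3, F2 replicate 2 or F3 replicate 4 (adjusted p = 0.0612, 0.377 and 0.478), and with the array set as a block (median −0.044, adjusted p = 0.0842). The insulin call ended without F2 replicates 3 or 4 or F3 replicates 3 or 4 (adjusted p = 0.0931, 0.0937, 0.174 and 0.0679).

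Fatty acid and triglyceride synthesis was the list called higher in F3 than in F2, with 16 of 24 members higher (median 0.09, adjusted p = 0.0368), and with adjusted p = 0.914 with an estimated correlation. Pklr was at 0.45 (SE 0.17) and Acly at 0.72 (SE 0.38, and 0.42 without F3 replicate 3). The median was −0.0031 without F2 replicate 2 (adjusted p = 0.9), and the call also ended without control replicate 3, F2 replicates 3 or 4, or F3 replicates 1 or 3 (adjusted p = 0.0796, 0.0552, 0.0546, 0.144 and 0.364). Exact permutation tests of list scores cannot give a p under 0.0286 with 4 arrays against 4, so 25 of the 43 lists would have to reach it for any to pass after adjustment. The smallest exact p was 0.0571, for DNA methylation and histone-modifying enzymes in F3 against F2 (difference of scores −0.034, adjusted p = 0.936) and for glycolysis and glycogen genes in F2 (adjusted p = 1). With the array set as a block the median of fatty acid and triglyceride synthesis was 0.0041 (adjusted p = 0.713), limma called 0 genes and camera 9 lists. Within the higher set its median was −0.01 (adjusted p = 0.728) and 0 genes were called, and within the lower set, with 1 F3 array, 3.

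Hepatocyte markers were called higher in F2 (12 of 14, median 0.03, adjusted p = 0.0084) with adjusted p = 0.654 with an estimated correlation, and in F3 (11 of 14, median 0.06, adjusted p = 0.039) with adjusted p = 0.93 with an estimated correlation. The secreted protein genes Apob, Apoa1 and Trf were at 0.09 (SE 0.057), 0.06 (SE 0.052) and 0.05 (SE 0.052) in F2, and in F3 Apob was at 0.10 (SE 0.057), Fgb at 0.16 (SE 0.094), Ttr at 0.07 (SE 0.056) and the hepatocyte transcription factor gene Hnf4a at −0.12 (SE 0.081). In F2 the hepatocyte call ended without control replicates 2 or 3 or F2 replicate 3 (adjusted p = 0.155, 0.252 and 0.0861). In F3 it ended without control replicates 2, 3 or 4, F2 replicate 4 or F3 replicate 4 (adjusted p = 0.219, 0.164, 0.097, 0.0549 and 0.258).

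Pericentral hepatocyte markers were called lower in F2 (11 of 13, median −0.15, adjusted p = 0.0161), and with adjusted p = 0.654 with an estimated correlation. Lgr5 and Axin2, targets of Wnt signalling, were at −0.19 (SE 0.12) and −0.18 (SE 0.14), Cyp1a2 at −0.21 (SE 0.14) and Aldh1a1 at −0.23 (SE 0.16, and −0.082 without F2 replicate 2). The call ended without control replicates 2, 3 or 4 or F2 replicate 2 (adjusted p = 0.0674, 0.0734, 0.115 and 0.968), and within the higher set the median was 0.02. Pancreatic acinar markers were called lower in F2 (11 of 11, median −0.07, adjusted p = 0.0368), and with adjusted p = 0.672 with an estimated correlation. Ctrl was at −0.09 (SE 0.063), Clps at −0.07 (SE 0.055), Ctrb1 at −0.11 (SE 0.13) and Cela2a at −0.06 (SE 0.073). Control replicate 3 had the highest acinar score (0.24), and the call ended without it (adjusted p = 0.988), without control replicate 4 (adjusted p = 0.105) or without F2 replicates 1, 3 or 4 (adjusted p = 0.0716, 0.159 and 0.078). Its high score was not particular to acinar markers. Control replicate 3 was also highest for skeletal muscle (0.29), T and NK cell (0.21), erythroid (0.20), cholangiocyte (0.19) and gallbladder and intestinal markers (0.13), though not for the remaining cell types.

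Markers of other cell types were not called in either generation. In F2 the medians were −0.0015 for periportal hepatocytes (adjusted p = 0.636), 0.03 for Kupffer cells and macrophages (adjusted p = 0.313), −0.02 for endothelial cells (adjusted p = 0.636), −0.02 for stellate cells and fibroblasts (adjusted p = 0.976) and 0.03 for cholangiocytes (adjusted p = 0.335). Blood cell markers stood at −0.02 for B cells (adjusted p = 0.701), −0.07 for T and NK cells (adjusted p = 0.313), −0.05 for neutrophils (adjusted p = 0.313) and −0.07 for erythroid cells (adjusted p = 0.294). Tissue contaminants stood at −0.05 for adipocytes (adjusted p = 0.492), −0.04 for skeletal muscle (adjusted p = 0.464), 0.02 for gallbladder and intestinal epithelium (adjusted p = 0.317) and −0.04 for mesothelial cells (adjusted p = 0.607). In F3 the largest of these shifts was −0.09, for T and NK cells (adjusted p = 0.0842).

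Taking both generations against control, the averaged descendants differed most in Cyp2b9 (−1.06, SE 0.66), the gene that stood apart in control replicate 2, and Cyp2c67 (0.34, SE 0.068) had the lowest p of the genes tested. Cyp8b1 was at −0.60 (SE 0.15) and Cyp2a4 at −0.63 (SE 0.25), and none passed. Apoa4, an apolipoprotein of triglyceride-rich particles chosen here after its value was seen, was at 0.62 (SE 0.18). Limma called 0 of 18725 genes (smallest adjusted p = 0.9998), with 279 at an unadjusted p under 0.05 (133 higher, 146 lower). The 95% interval lay within 2-fold for 98.9% of genes, again with genes near background included.

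Across the 18725 genes, the F2 and F3 differences from control correlated with r = 0.443, and 68.0% of genes had the same sign. Both differences use the same 4 control arrays. Simulated unchanged groups that shared their controls gave a mean r of 0.471 (95% range −0.188 to 0.906) and 66.7% of the same sign. The simulated controls were not these 4 arrays, since residuals of all arrays were shuffled over the groups. The shuffles could mix the small structural RNA sets in any proportion, so the range is a rough guide for the real groups. The covariance was 0.00464 against 0.0101 simulated. Without F2 replicate 1 the r was 0.224, without F2 replicate 4 it was 0.282, and without control replicate 2 it was 0.679. With 2 control arrays used for each difference, r was −0.310 on average (−0.602 to −0.0925 over 6 splits). The difference between the 2 pairs of controls enters the F2 and F3 differences with opposite signs, which pulls r down compared with shared controls. No range for unchanged groups was made for this value, so it does not show that F2 and F3 differ from control in opposite ways.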

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

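The tests on the acute phase genes of F2 replicate 2 and on the lists called at the preset correlation were chosen after the results were seen. Within each group of 4 arrays, a value was singled out where its gap to the nearest other array exceeded Dixon's 95% critical value. Chance does this for about 1 in 20 groups, or 21.75 of the 435 groups tested, and 35 were found. Many of the genes were named by their values on the same arrays, and genes vary together, so 21.75 is a rough guide. F2 replicate 2 accounted for 14 and control replicate 2 for 7.

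F2 replicate 2 stood above the other F2 arrays for several genes and below them for others. Its log2 levels were high for Cp (10.07, others 9.73 to 9.75), Crp (10.69, others 9.91 to 10.04), Fgb (12.87, others 12.47 to 12.50), Fgg (12.96, others 12.56 to 12.59), Trf (13.04, others 12.94 to 12.95) and Ldha-ps2 (9.39, others 8.85 to 8.92). They were low for Cyp2a4 (9.57, others 10.77 to 10.997), Cyp8b1 (9.55, others 10.22 to 10.29), Map3k13 (6.75, others 7.39 to 7.41), Ppara (9.60, others 9.99 to 10.03), Slc22a28 (9.42, others 9.80 to 9.87) and Slco1a4 (5.14, others 6.48 to 6.55). Its score was 0.97 for the acute phase response (others −0.16 to −0.07) and −0.32 for pericentral hepatocyte markers (others 0.03 to 0.08).

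All 27 acute phase genes lay above their mean in F2 replicate 2, and 24 were at their highest of the 12 arrays there. The serum amyloid gene Saa2 stood 3.71, Lcn2 3.51, Saa1 3.21 and Apcs 3.13 above the mean of the other arrays. A rise shared by all F2 arrays did not account for it. The 3 other F2 arrays lay below the highest control array (0.32). An effect of descent that shows in only some descendants stays open, since the other F2 arrays cannot test it. The lower set of small structural RNA did not account for the full size of the rise in F2 replicate 2. The other arrays of that set ran from −0.118 to 0.321 (median 0.119). Arrays of the higher set ran from −0.355 to 0.0833, so a smaller part that follows the set stays open. Neutrophils were not excluded, since 6 of 8 of their markers lay above their mean there (median 0.0942) at a median level of 5.20, below the first quartile of all genes (5.35), and a change in Kupffer cells (score 0.447) or an inflammatory response in the donor may remain too, the last 2 untested.

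Control replicate 2 stood apart from the other controls, above them for Cyp2b9 (8.50, others 4.07 to 4.27), Ehhadh (12.03, others 9.97 to 10.26), Mgll (9.29, others 8.72 to 8.77), Plin4 (6.57, others 5.81 to 5.86) and the NRF2 target score (0.50, others −0.05 to 0.02). It lay below them for the male-biased genes Hsd3b5 (8.18, others 10.42 to 10.75) and Susd4 (7.10, others 7.92 to 7.93).

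F2 replicate 1 was high for the lipogenic genes Acly (9.72, others 8.35 to 8.56) and Pnpla3 (6.24, others 5.50 to 5.56) and for Pgd (6.96, others 6.61 to 6.63), and low for the insulin signalling gene Irs2 (8.42, others 9.14 to 9.24). F2 replicate 4 was high for Cidea (5.78, others 5.45 to 5.48) and Lgr5 (6.12, others 5.95 to 5.98). Among controls, replicate 1 was high for Tnfaip3 (5.74, others 5.17 to 5.24) and the immediate early gene score (0.14, others −0.04 to −0.01), and replicate 3 was low for Atp5a1 (10.70, others 10.74 to 10.74) and Ttr (12.30, others 12.43 to 12.44). Among F3 arrays, replicate 1 was low for Arsg (6.32, others 6.49 to 6.50) and high for Cyp2b9 (4.49, others 4.15 to 4.18), replicate 3 was high for Nudt7 (11.70, others 11.46 to 11.49) and replicate 4 for Cp (9.997, others 9.72 to 9.76).

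The F2 and F3 effects against the same controls differed for 8 gene lists by camera with the preset correlation. The adjusted p was 0.0368 for fatty acid and triglyceride synthesis, 0.000163 for fatty acid oxidation, 0.000324 for lipid droplet genes, 0.0311 for insulin and IGF signalling, 0.034 for inflammatory cytokines, 0.00213 for immediate early genes, 0.000163 for glucocorticoid targets and 0.000172 for heat shock proteins. With an estimated correlation the adjusted p was 0.914 for each.

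The number of lists called at the preset correlation may come from genes of a list that vary together between samples more than that correlation allows. Estimated correlations ran from 0.0164 to 0.879 (median 0.294) and exceeded the preset 0.01 for 43 of 43 lists, and 0 of the 29 calls remained when camera used them. On lists with no simulated effect the preset correlation called 12.8 of 43 on average. A biological shift in some lists stays open, since camera with the estimated correlations does not show that the groups are alike.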

How the results depend on the processing

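The array set as a block, each array set alone and the fit without both control replicate 2 and F2 replicate 2 were chosen after seeing the data. Signal over background was moderate: positive control probe sets were separated from negative ones with an area under the curve between 0.891 and 0.905, which limits what can be said of dim genes. The cause was not tested for the changes given here, except where fewer arrays, a looser threshold or another assumed correlation is the alternative itself.

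The 0 genes called in each comparison stayed at 0 under quantile normalization, median centring, both filters, the mean over probe sets, trend and robust fits, array weights, the groups compared alone and leaving out each array (0 to 0). An unadjusted p under 0.05 with a 1.5-fold difference gave 9 genes in F2, 8 in F3, 4 in F3 against F2 (Thrsp, Gm23340, Fasn and Angptl4) and 4 for the averaged descendants (Cyp8b1, Apoa4, Cyp2a4 and Serpina12). Those genes were named after their values were seen.

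With the replicate number as a block, camera called 13 lists in F2, 6 in F3 and 8 in F3 against F2, and limma 0 genes (140, 409 and 341 at an unadjusted p under 0.05), while the metabolic list gave 0 genes in F3 (Cyp8b1, −0.71, adjusted p = 0.0702 over the list alone). Same numbers did not pair the arrays: residual correlations of equal numbers ran from −0.51 to 0.32, and 0 arrays correlated best with their own number.

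Lists called were 0 in all 3 comparisons with an estimated correlation and 0 with fry. In F3 they were 4 with the stricter filter, and in F2 they were 9 with array weights. An adjusted p under 0.10 gave 13 in F3 and 13 in F3 against F2. With the array set as a block they were 14 in F3. In the higher set alone they were 18 in F3 and 15 in F3 against F2, in the lower set alone 13 and 20, and without both arrays 4 and 14. Leaving out each array gave 10 to 18 lists in F2, 4 to 16 in F3 and 6 to 14 in F3 against F2. Of 811 refits of called lists 604 kept the call, 188 lost it and 19 turned direction. This total includes an adjusted p under 0.10, which cannot end a call (29 of 29 kept). The estimated correlation and fry each ended 29 of 29, so the total is no measure of how firm the calls are. Of 4527 refits of named genes 31 turned direction by at least the SE of the difference. Smaller turns of genes were more frequent and are left out below: leaving out 1 array alone gave 55 turns of any size, in 25 of 175 gene values.

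The metabolic list gave 0 to 1 genes in each comparison on leaving out each array. Quantile normalization gave 1 gene in F3 against F2 (Cpt1a) and array weights 2 in F2 (Cpt1a and Pck1). The higher set alone gave 0 in F3. The lower set alone gave 1 in F2 (Fasn), 0 in F3 and 2 in F3 against F2 (Cyp7a1 and Fasn), and limma called 2 genes there in F3, 3 in F3 against F2 and 1 for the averaged descendants. Without both arrays the list gave 3 genes in F3 against F2 (Cd36, Cpt1a and Cyp8b1).

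The correlation of F2 and F3 differences turned to −0.310 with separate controls, a value with no range for unchanged groups and pulled down by the difference between the control pairs. It was 0.618 in the higher set and 0.712 without both arrays, and ranged from 0.224 to 0.679 on leaving out each array.

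Directions turned for these values, for single genes by at least 1 SE. With array weights female-biased genes in F2 were at 0.044 and Lepr in F3 at 0.25. In the higher set alone, pericentral markers (0.023) and Plin2 (−0.088) turned in F2, cytokines (0.033), Ccl2 (0.041), Igfbp1 (0.61) and Irs2 (0.33) in F3, and fatty acid synthesis (−0.012), Cyp7a1 (−0.30), Igfbp1 (0.31) and Irs2 (0.23) in F3 against F2. In the lower set alone, cholesterol synthesis (0.015), male-biased genes (−0.035), Mvk (0.012) and Rps15 (0.064) turned in F2, NRF2 targets (0.092), heat shock proteins (0.066), Cyp7a1 (0.46), Gstm3 (0.41), Igf1 (−0.049) and Ugdh (0.045) in F3, and heat shock proteins (0.066), Cpt2 (0.15), Lepr (−1.13), Pnpla3 (−0.14) and Tsc2 (0.091) in F3 against F2. Without both arrays, oxidative phosphorylation (0.0015), female-biased genes (0.076), the acute phase response (−0.11), Aldh1a1 (0.046), C8a (−0.0086), Cd36 (0.55), Cyp3a44 (0.052) and Slco1a4 (0.048) turned in F2, fatty acid oxidation (0.030) and Plin2 (0.13) in F3, and fatty acid synthesis (−0.0031) in F3 against F2.

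Leaving out 1 array turned these directions, for single genes by at least 1 SE, given with the lowest and highest value over the arrays left out. The end that turned came without control replicate 2 for male-biased (−0.035 to 0.13), female-biased (−0.28 to 0.0077), Cd36 (−0.35 to 0.42) and Hsd3b5 values (−0.031 to 0.83) in F2, and for fatty acid oxidation (−0.19 to 0.030) and Plin2 (−0.17 to 0.13) in F3. It came without control replicate 1 for Igfbp1 (−0.46 to 0.52 in F2, −0.69 to 0.29 in F3), without F2 replicate 2 for the acute phase response (−0.052 to 0.40) and fatty acid synthesis in F3 against F2 (−0.0031 to 0.18), and without F3 replicate 3 for Pnpla3 in F3 (−0.38 to 0.43) and G6pc in F3 against F2 (−0.14 to 0.19).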

Other observations

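The tests on the small structural RNA sets were chosen after the sets were seen, and the count of splits for the metabolic gene list was added after its call was seen. Control replicate 2 stood above the other arrays for genes of fat oxidation and sterol synthesis. Against the mean of the other 11 arrays, the fatty acid hydroxylase gene Cyp4a14 stood 4.42 higher on the log2 scale, the peroxisomal transporter gene Abcd2 3.06, the thioesterase genes Acot3 2.94 and Acot1 2.28, and Pdk4, which restrains glucose oxidation, 1.397. Among sterol genes, Sqle, squalene epoxidase, stood 2.95 higher, Hmgcs1 2.47 and Idi1 2.40, and 18 of 18 cholesterol synthesis genes lay above their mean. These are values of 1 array and were singled out after they were seen.

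In F2 replicate 2, 3 of 17 heat shock genes and 3 of 24 genes of fatty acid and triglyceride synthesis lay above the mean of the other arrays, an untested count. Hspa1a was at −1.50, Hsph1 at −1.37, Thrsp at −1.27 and Fasn at −1.13 against the mean of the other arrays, while the metallothionein genes Mt2 and Mt1 were 3.24 and 2.21 higher. Within the lower set of arrays, which holds 1 F3 array assumed to vary like the other groups, limma called Obp2a, an odorant-binding protein gene (4.27, adjusted p = 5.27e-05), and Treh, trehalase (1.87, adjusted p = 0.0434), in F3 against control. Against F2 it called Obp2a (4.41, adjusted p = 4e-05), Treh (1.80, adjusted p = 0.0468) and the whey acidic protein family gene Wfdc12 (1.81, adjusted p = 0.0468), and for the averaged descendants Obp2a (2.06, adjusted p = 0.00249). These rest on F3 replicate 4 alone and were named after their values were seen.

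The division of the arrays by small structural RNA did not follow descent, since 3 of 3 groups had arrays in both sets. Hybridisation controls differed by 0.0065 (SE 0.07) between sets in the deposited values, against 0.43 for small nucleolar RNAs, the class that defined the sets. These values were already processed by unknown steps, so brightness at hybridisation or scanning before them cannot be judged. Recovery or labelling of short RNA may account for the division, since the 3 other classes tested (ribosomal, small nuclear and Y RNA) separated the same sets. Not every short class followed the first principal component, which parts the sets. Its median r was −0.17 for microRNAs (252 genes) and 0.25 for guide RNAs (23 genes), against 0.64 for small nucleolar and 0.96 for Y RNAs. A biological difference between the samples that moves these classes together stays open.

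Other splits of the same arrays were fitted to ask whether chance can be excluded for each count. Where the real count is 0, every split gives at least as many, so those shares say nothing about chance. For F2 against control, 35 of 35 splits gave at least the real 0 genes and 17 of 35 gave at least the real 14 lists, with highest others of 521 genes and 22 lists. The split that called 521 genes parted the arrays by the small structural RNA sets, so it points to that structure of the samples, and with the set as a block limma called 0 genes for the real groups. For F3 against control, 35 of 35 splits gave at least 0 genes (highest other 1) and 35 of 35 at least the real 7 lists (highest other 20). For F3 against F2, 35 of 35 gave at least 0 genes (highest other 0) and 31 of 35 at least the real 8 lists (highest other 23). For the averaged descendants, 100 of 100 drawn splits gave at least 0 genes (highest other 0). For the metabolic list in F3, 6 of 35 splits called at least the real 1 gene, Cyp8b1, with a highest other of 4. Chance could not be excluded for the 3 counts of lists or for the metabolic list.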
